A study of Mus musculus with 48 samples.

How the data were processed

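RNA of 4 brain tissues of male C57BL/6 mice (SN/VTA, PFC, STR and HAB) was measured at 6 times of day in 2 successive 24-h cycles, on 48 Affymetrix Mouse Gene 2.0 ST arrays. Per the labels, tissue was dissected from coronal slices, total RNA was isolated with RNeasy columns, RNA of 3 mice of the same time was pooled for each array, and the pool was turned into biotin-labelled cDNA with the WT Pico kit. The deposited values of the authors were taken as log2 levels per probe set, since they ran from 1.09 to 13.65 with array medians from 5.84 to 6.07; the background correction, summarisation and normalization between arrays are not given in the sources used here. All 48 columns of the table matched a sample by name, and 0 columns were not used. No detection calls were used, so the limit set by background is unknown. The number of arrays limits the precision.

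The table held 41345 rows. The platform annotation listed 25335 of them, 23521 with 1 gene symbol and 1814 with several, and the other 16010 are unnamed here. By Entrez identifier 23328 rows matched the RefSeq gene table, and its symbol differed from that of the platform for 0 of them. Rows with several symbols were left out of the gene tests, so that Per2, Csnk1d, Ppp1r1b, Rbm3, Dnaja1, Pdia4, Idi1, Kcnj13, Hba-a1, Hbb-bs, Alas2 and Cd74 of the gene lists were not analysed here. Some list genes are not reported here, and others had a mean below the filter, among them Ier2, Gpr151, Slc6a4 and Tdo2. For the 1082 genes with several rows, the row with the highest mean was taken, which left 22180 genes. Of these, 17274 had a mean over the 48 arrays at or above 5.05, the 30th percentile of all rows, and were tested.

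Tests were run in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) and the data.table package in version 1.17.8, and figures were drawn in Python 3.11.15 with matplotlib 3.10.9. A rhythm in a tissue was the joint F test of the cosine and sine of a 24-h period over the 12 arrays of that tissue, with 9 residual degrees of freedom; amplitude is given from the mean to the peak of the fitted curve on the log2 scale, and the fold from trough to peak. The shared rhythm used all 48 arrays with tissue as a term, the difference of rhythms the 6 tissue by cosine and tissue by sine terms, and dark against light the mean of ZT15, ZT19 and ZT23 minus that of ZT03, ZT07 and ZT11 within a tissue. Each tissue was set against the mean of the other 3 in a model of 24 groups of tissue and time, with a change of at least 1 on the log2 scale required. All p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05.

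Gene lists of 23 pathways, cell types and neighbouring tissues were fixed, and the tests, the rule for named genes and the alternatives were chosen, before the data were examined. The lists were core clock, immediate early genes, dopamine synthesis and midbrain dopamine neurons, dopamine breakdown, dopamine receptors and striatal signalling, cortical glutamatergic neurons, habenula neurons, heat shock proteins, cold-inducible RNA-binding proteins, ER chaperones and unfolded protein response, glucocorticoid-responsive genes, cholesterol synthesis, oligodendrocytes, astrocytes, microglia, endothelial cells, ependymal cells, choroid plexus, thalamus, hippocampus, pineal gland, serotonin neurons and blood. Lists of at least 5 measured genes were tested with camera at a preset correlation of 0.01 on the signed contrasts, and again with an estimated correlation. Of 51 camera calls 10 held with the estimated correlation: ER chaperones in the dark in PFC; dopamine synthesis in SN/VTA and PFC; habenula genes in PFC and HAB; dopamine receptors in STR and HAB; and microglia, ependymal and hippocampus genes in HAB. The direction of the list median was the same under both other scalings for all 51 calls. Rhythmic members of a list were counted against all genes tested with Fisher's exact test, two-sided, with p-values adjusted over lists and tissues. This test takes the members of a list as independent, so its p-values can be too small where members move together.

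Genes were named by rule: the 10 largest amplitudes past the threshold per tissue and for the shared rhythm, all core clock genes, the 3 highest and 3 lowest changes between dark and light, the 10 smallest p for the difference between tissues, the 8 highest and 3 lowest changes per tissue, and at most 4 members of each list. Predicted genes, short RNAs, receptor families of smell and immune receptor segments were passed over. Hrh3, the dopamine genes given with values below the threshold in SN/VTA, and Sgk1 there were chosen after their values were seen.

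Replicate numbers marked the 24-h cycle in which the mice were killed, per the labels. The tests held no term for this number, and fits with it as a block were run as alternatives. Deviations from the group means correlated with a mean r of 0.0357 over 60 pairs of the same tissue and number and 0.0357 over 36 pairs of different tissues at the same hour. By tissue the first was 0.0719 in SN/VTA, -0.0207 in PFC, -0.00137 in STR and 0.0932 in HAB, where 7 of 15 pairs lay above 0.1 and the highest r was 0.410. Whether the 4 tissues came from the same mice is not given in the sources used here. No gene passed the threshold for a difference between the cycles in any tissue in limma. In SN/VTA, PFC, STR and HAB the smallest adjusted p of that limma test was 0.198, 0.525, 0.947 and 0.0506. In that order 1813, 726, 822 and 1400 genes had an unadjusted p under 0.05. Choroid plexus genes in HAB did differ between the cycles as a list, as given below.

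Each test was tried on simulated data of 17274 genes with 200 changed. For rhythms of amplitude 0.2 and 0.4, 52% and 89% were called in SN/VTA with 11 false calls of 152, 20% and 71% in PFC with 6 of 97, 14% and 66% in STR with 4 of 84, and 17% and 70% in HAB with 2 of 89. The shared test called 96% and 97% with 11 false of 204, and the test of the difference 11% and 61% with 22 false of 94, above its 5% target. For dark against light changes of 0.4 and 0.8, 88% and 100% were called in SN/VTA (11 false of 199), 69% and 97% in PFC (12 of 178), 70% and 94% in STR (11 of 175) and 72% and 96% in HAB (12 of 180). For tissue differences of 1.2 and 2.2, 80% and 100% were called in SN/VTA (4 false of 797), 63% and 98% in PFC (0 of 1058), 74% and 99% in STR (2 of 554) and 78% and 100% in HAB (7 of 535).

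Alternatives tried were no filter and a filter at the median of all rows (5.98), quantile normalization again, centring on array medians, trended and robust eBayes, replicate number as a block, 1 model of all 48 arrays, tests with no assumed shape, a rank test over 6 phases, dark against light without ZT11 and ZT23, and leaving out cycles, tissues and single arrays. Added after the data were seen were the tissue mean per hour, the tissue contrasts without short RNA genes, the tissue contrasts within 1 cycle with times as additive terms, and the mean of the choroid plexus genes as a covariate.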

Results

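RNA was measured in 4 parts of the dopamine system of male C57BL/6 mice kept in 12 h of light and 12 h of darkness: the substantia nigra with the ventral tegmental area (SN/VTA), the prefrontal cortex (PFC), the striatum (STR) and the habenula (HAB). Each part was collected every 4 h over 2 successive days, at Zeitgeber times (ZT, hours after lights on) 3, 7 and 11 in the light and 15, 19 and 23 in the dark. Replicate 1 came from the first 24-h cycle and replicate 2 from the second, so that each tissue had 12 arrays and the study 48. Each array carried RNA pooled from 3 mice, so p-values below measure the spread between pools, and the number of arrays limits the precision. Values were on the log2 scale, from 1.09 to 13.65, with array medians from 5.84 to 6.07. Replicates of the same tissue and time correlated with r between 0.982 and 0.995 across the 17274 genes tested, and all 12 arrays of each tissue correlated best with arrays of that tissue. Of the 17274 genes tested, those named here were taken by a rule given with the processing, unless stated otherwise.

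The first comparison asked which genes set each part of the dopamine system apart from the other 3. The contrasts of a gene cancel out over the 4 tissues, so a gene far higher in 1 tissue is lower in others by construction. A lower value below is thus not independent of a higher one elsewhere. SN/VTA was marked by the genes of dopamine neurons. Slc6a3, the dopamine transporter, was 45.4-fold above the mean of the other tissues (log2 difference 5.50 ± 0.05 SE). Th, which makes the dopamine precursor, was 18.8-fold higher (4.23 ± 0.06) and Slc18a2, which loads monoamines into vesicles, 15.4-fold (3.94 ± 0.06). The nicotinic receptor subunit Chrna6 was higher by a log2 difference of 3.60, at 9.13 against 5.35 in PFC, 5.52 in STR and 5.72 in HAB. No background measure was used, so folds here are between deposited levels and are lower bounds where the lower level lies near background. In all 12 SN/VTA arrays Slc6a3 lay above all 36 arrays of the other tissues. In all, 389 genes were higher and 224 lower in SN/VTA by at least 1 on the log2 scale at an adjusted p under 0.05 in limma. Centring each array on its median gave 639 higher and 143 lower (81.7% higher in place of 63.5%), because it moved the median of all genes in this contrast from 0.05 to 0.20.

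Of the 19 measured genes of dopamine synthesis and midbrain dopamine neurons, 11 were higher in SN/VTA, and 11 adjusted over the list alone (camera in limma, adjusted p = 4.59e-08, and adjusted p = 0.00243 with an estimated correlation). Ret, a receptor for neurotrophic factors, was higher by 2.81 and Aldh1a1, which oxidises aldehydes, by 2.57. Genes of myelin-forming oligodendrocytes were also higher, 6 of 9 (6 adjusted over the list alone), among them Mog by 1.86, Mag by 1.46 and Cnp by 1.34. For this list camera gave an adjusted p of 7.92e-05, and adjusted p = 0.32 with an estimated correlation. Among thalamus markers, 4 of 8 were higher (4 adjusted over the list alone), led by the vesicular glutamate transporter Slc17a6 (2.37), Tcf7l2 (1.93) and Prkcd (1.88). Their camera result was an adjusted p of 0.00453, and adjusted p = 0.384 with an estimated correlation. Astrocyte markers were higher for 2 of 9 (2 adjusted over the list alone; camera adjusted p = 0.0259, and adjusted p = 0.373 with an estimated correlation). The glycine receptor subunit Glra1 (3.51) and the neuropeptide Rln3 (3.43) were further genes at the top. Cortical neuron genes were lower for 6 of 8, and 6 adjusted over the list alone, with Tbr1 at -2.21 (camera adjusted p = 4.96e-04, and adjusted p = 0.107 with an estimated correlation). Immediate early genes were lower for 5 of 14, and 5 adjusted over the list alone (1.54e-06, and adjusted p = 0.093 with an estimated correlation). Dopamine receptor and striatal genes went both ways, 1 of 15 higher and 2 lower (3 adjusted over the list alone), with Drd1 at -1.83 and Drd2 at 1.06 (camera adjusted p = 2.77e-04, and adjusted p = 0.101 with an estimated correlation). No endothelial gene of 8 passed the threshold of 1, with a median of -0.24 (0.040, and adjusted p = 0.391 with an estimated correlation). Ddn (-2.88), Gda (-2.49) and Ano3 (-2.37) were the lowest of the genes named by rule.

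PFC was marked by genes of cortical projection neurons. Fezf2, a transcription factor of deep-layer neurons, was 8.53-fold above the other tissues (3.09 ± 0.11), and Neurod6 was higher by 2.70, Tbr1 by 2.55 and Lamp5 by 2.27. Of 8 measured cortical neuron genes 6 were higher, and 6 adjusted over the list alone (camera adjusted p = 3.90e-04, and adjusted p = 0.101 with an estimated correlation). Fezf2 was above all 36 other arrays in all 12 PFC arrays. The largest difference among the genes named by rule, which leaves out short RNAs, was that of Ccn3, a secreted matrix protein, at 9.52-fold (3.25 ± 0.10), and the neuropeptide Vip was higher by 2.87. In all, 403 genes were higher and 508 lower.

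Immediate early genes, which neurons switch on when active, were higher in PFC for 5 of 14 (5 adjusted over the list alone; camera in limma adjusted p = 7.92e-05, and adjusted p = 0.134 with an estimated correlation). Genes of dopamine synthesis and midbrain dopamine neurons were lower for 8 of 19 (8 adjusted over the list alone; 7.92e-05, and adjusted p = 0.0267 with an estimated correlation), with Slc18a2 at -2.25. Habenula genes were lower there for 10 of 13 (10 adjusted over the list alone; 3.15e-04, and adjusted p = 0.0267 with an estimated correlation), with Calb2 at -3.18. Hippocampus markers were lower for 5 of 7 (5 adjusted over the list alone; 6.90e-04, and adjusted p = 0.101 with an estimated correlation). Thalamus markers were lower for 5 of 8 (5 adjusted over the list alone; 0.00817, and adjusted p = 0.398 with an estimated correlation), as were oligodendrocyte genes for 3 of 9 (3 adjusted over the list alone; 0.00461, and adjusted p = 0.467 with an estimated correlation). Choroid plexus genes were lower for 5 of 8, and 5 adjusted over the list alone, without a camera call (adjusted p = 0.0819). Dopamine receptor and striatal genes were lower for 3 of 15 (3 adjusted over the list alone; camera adjusted p = 0.00100, and adjusted p = 0.134 with an estimated correlation), with Drd2 at -2.40. Ependymal genes were lower for 2 of 5 (2 adjusted over the list alone; 0.0398, and adjusted p = 0.214 with an estimated correlation). Slitrk6 (-3.09) and the telomerase RNA Terc (-3.07) were among the lowest.

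STR was marked by the genes of medium spiny neurons, its main cell type. The dopamine receptor Drd1 was 12.0-fold above the other tissues (3.58 ± 0.06), the opioid peptide precursor Penk 8.80-fold, Drd2 8.47-fold, and Rgs9, which shortens G protein signalling, was higher by 3.12. In all 12 STR arrays Drd1 lay above all 36 others. Of 15 measured genes of dopamine receptors and striatal signalling, 13 were higher, and 13 adjusted over the list alone (camera in limma adjusted p = 2.49e-12, and adjusted p = 0.00243 with an estimated correlation). In all, 177 genes were higher and 200 lower; median centring gave 135 higher and 286 lower (32.1% higher), with a median of all genes of -0.12 in place of -0.02.

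The transcription factor Rxrg (3.04) and Dlx5 (2.87), a homeobox gene of inhibitory neurons, were further genes higher in STR. Thalamus markers were lower for 5 of 8 (5 adjusted over the list alone; camera in limma adjusted p = 0.00368, and adjusted p = 0.384 with an estimated correlation). Genes of dopamine synthesis and midbrain dopamine neurons were lower in STR for 5 of 19 (5 adjusted over the list alone; 0.0114, and adjusted p = 0.134 with an estimated correlation). Habenula genes went both ways, 3 of 13 higher and 5 lower (8 adjusted over the list alone; 0.0248, and adjusted p = 0.134 with an estimated correlation). Among those higher was the choline transporter Slc5a7 (1.56), a gene of cholinergic neurons in either tissue. The median cholesterol synthesis gene lay at -0.43, with none of 13 past the threshold of 1 (camera adjusted p = 8.23e-05, and adjusted p = 0.134 with an estimated correlation). In SN/VTA that median was 0.40 (0.00266, and adjusted p = 0.315 with an estimated correlation). Immediate early genes were higher for 1 of 14, and 1 adjusted over the list alone (camera adjusted p = 0.0193, and adjusted p = 0.398 with an estimated correlation). Astrocyte markers were lower for 1 of 9, and 1 adjusted over the list alone (0.0223, and adjusted p = 0.370 with an estimated correlation), and the median heat shock gene lay at -0.28 with none past 1 (0.040, and adjusted p = 0.320 with an estimated correlation). The neuritin gene Nrn1 (-3.16), Cpne9 (-2.70) and Neurod6 (-2.64) were lowest in STR.

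HAB was marked by nicotinic receptor subunits and a tachykinin. Chrna3 was 13.2-fold above the other tissues (3.73 ± 0.05), Chrnb4 10.1-fold (3.34), the neurokinin B precursor Tac2 was higher by 3.30 and Pou4f1, a transcription factor of habenula neurons, by 2.81. Chrna3 was above all 36 other arrays in all 12 HAB arrays. Of 13 measured habenula genes, 11 were higher, and 11 adjusted over the list alone (camera in limma adjusted p = 3.66e-12, and adjusted p = 8.64e-05 with an estimated correlation). In all, 242 genes were higher and 117 lower.

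Lists named for structures near the habenula were also higher in HAB. These levels do not tell whether habenula cells or neighbouring tissue gave them, and thalamus markers were higher in SN/VTA too. Hippocampus markers were higher for 6 of 7 (6 adjusted over the list alone; camera in limma adjusted p = 8.70e-06, and adjusted p = 0.0287 with an estimated correlation), with Dsp at 3.06, Lct at 2.97, C1ql2 at 2.52 and Prox1, a marker of dentate granule cells, at 2.36. Thalamus markers were higher for 6 of 8 (6 adjusted over the list alone; 3.15e-04, and adjusted p = 0.274 with an estimated correlation), with Tcf7l2 at 2.02. Choroid plexus genes were higher for 5 of 8 (5 adjusted over the list alone; 6.90e-04, and adjusted p = 0.384 with an estimated correlation). The thyroxine carrier Ttr was 11.2-fold higher (3.49 ± 0.38), Kl was higher by 2.72 and Sostdc1 by 2.01. Only 7 of the 12 HAB arrays lay above all 36 others for Ttr, whose level was 11.98 ± 1.39 in HAB (SD, n = 12), 10.07 ± 1.31 in SN/VTA, 8.01 ± 1.28 in STR and 7.38 ± 0.38 in PFC. Ependymal genes were higher for 2 of 5, and 2 adjusted over the list alone, with Tmem212 at 1.79 and Dynlrb2 at 1.44 (camera adjusted p = 3.73e-04, and adjusted p = 0.0287 with an estimated correlation). The serotonin receptor Htr5b was higher by 2.88; the serotonin neuron list had 3 measured genes and was not tested as a set.

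Cortical neuron genes in HAB went both ways, 3 of 8 higher and 1 lower (4 adjusted over the list alone; camera in limma adjusted p = 0.299). Dopamine receptor and striatal genes were lower for 6 of 15 (6 adjusted over the list alone; 8.43e-08, and adjusted p = 0.0253 with an estimated correlation), with Penk at -2.32. Of 19 genes of dopamine synthesis and midbrain dopamine neurons 4 were lower, Slc6a3 among them at -1.97, and 1 was higher (5 adjusted over the list alone; 0.00214, and adjusted p = 0.093 with an estimated correlation). Slc6a3 lay below all arrays of the other tissues in 0 of 12 HAB arrays, and Penk in 12. The low value of Slc6a3 thus reflects its high level in SN/VTA. The transcription factor Meis2 was at -2.85. The median microglia gene lay at -0.38, with none of 9 past the threshold of 1 (camera adjusted p = 4.14e-04, and adjusted p = 0.0442 with an estimated correlation). No pineal gland gene of 6 measured, no dopamine breakdown gene of 4 and no blood gene passed in any of the 4 tissue contrasts.

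**Figure D1:**
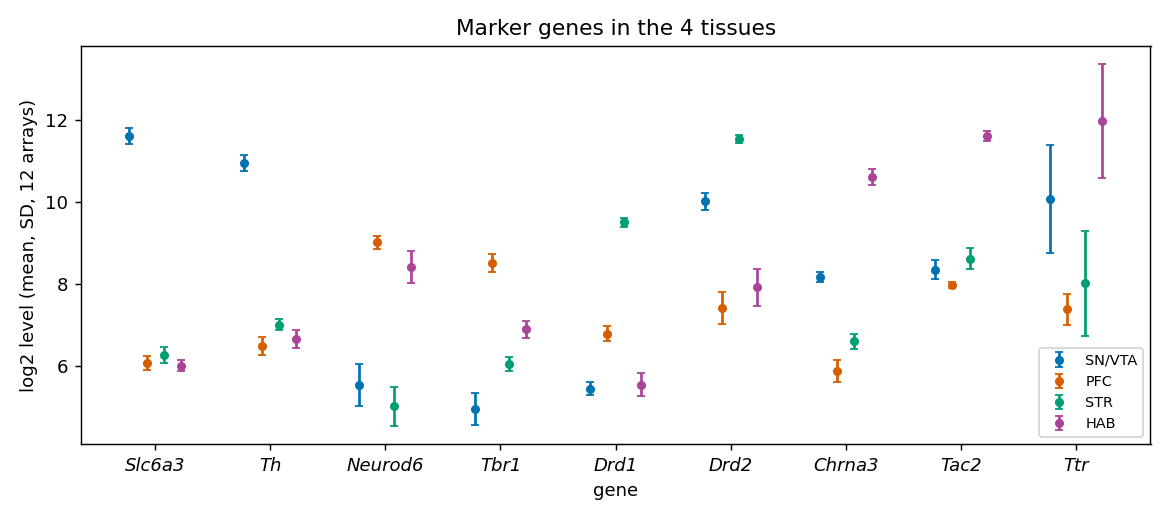
Levels on the log2 scale (vertical axis) of 9 marker genes in each of the 4 tissues; points give the mean and error bars the SD of 12 arrays per tissue. Slc6a3 and Th stand highest in SN/VTA, Neurod6 and Tbr1 in PFC, Drd1 and Drd2 in STR and Chrna3 and Tac2 in HAB, while Ttr spreads most in HAB (SD 1.39) and SN/VTA (1.31).

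The second comparison asked which genes followed a 24-h rhythm in each tissue. In SN/VTA, genes of the circadian clock led. Ciart, a repressor in the clock, had an amplitude of 0.51 ± 0.06 (log2, SE) and peaked at ZT11.2, a 2.03-fold change from trough to peak (limma adjusted p = 0.0108; 10 of 12 arrays lay on the side of the tissue mean that the fitted curve gave). Dbp, a clock output transcription factor, had an amplitude of 0.44 ± 0.05 with a peak at ZT11.1 (1.85-fold, adjusted p = 0.00907 in limma, 12 of 12 arrays). Per1 had one of 0.41 ± 0.04 at ZT12.5 and Nr1d1, which represses Arntl, one of 0.35 ± 0.04 at ZT8.3 (limma adjusted p = 0.00907; 12 of 12 arrays). Outside the clock, Fabp7, a fatty acid binding protein of astrocytes, peaked at ZT3.5 (0.29 ± 0.03), the cold-inducible RNA-binding protein Cirbp at ZT9.1 (0.29), the matrix protease Mmp14 at ZT1.1 (0.41) and the myelin gene Opalin at ZT5.2 (0.30). Fam83d (0.41, ZT13.7), the synaptic adhesion gene Lrrtm1 (0.32, ZT13.8) and the linker histone H1f2 (0.31, ZT2.9) completed the named genes.

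In SN/VTA 28 genes passed, 16 with a peak in the light and 12 in the dark, and 1705 had an unadjusted p under 0.05. Of the 28, 10 peaked between ZT11 and ZT15. Of 21 measured core clock genes 7 passed, and 15 adjusted over the list alone (Fisher's exact test, adjusted p = 1.42e-13). Per3 peaked at ZT12.8, Usp2 at ZT12.6 and Nr1d2 at ZT13.0. None of the 19 genes of dopamine synthesis and midbrain dopamine neurons passed in limma, and none adjusted over the list alone. Th had a fitted amplitude of 0.18 ± 0.06 with adjusted p = 0.431 in limma, Slc6a3 of 0.20 ± 0.05 with 0.319, Slc18a2 of 0.18 ± 0.05 with 0.340 and Ddc of 0.15 ± 0.06 with 0.578. Drd2, the autoreceptor of these neurons, had 0.22 ± 0.05 with 0.238. The glucocorticoid-induced kinase Sgk1 had 0.60 ± 0.10 at ZT12.8 with 0.0718. Adjusted over the list alone, 9 of 12 glucocorticoid-responsive genes and 10 of 13 ER chaperone genes passed, none over all genes. With replicate number as a block 18 genes passed, and H1f2 (adjusted p = 0.0612), Per3 (0.0671) and Usp2 (0.0729) were lost in limma. Every array left out but that of ZT07 replicate 1 (21 genes) moved the count by over 1.5 times: it was 14, 10, 12, 13 and 11 without ZT11, ZT15, ZT19, ZT23 and ZT03 of replicate 1 and 8, 18, 18, 15, 10 and 14 without ZT11, ZT15, ZT19, ZT23, ZT03 and ZT07 of replicate 2. A rank test called 0 and each cycle alone 0. On 12 arrays that rank test cannot pass a few genes alone, and 1 cycle holds 1 array per time, so both say little.

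In PFC clock genes passed as well, though others given below had larger amplitudes there. Dbp, Ciart and Nr1d1 had larger fitted amplitudes than in SN/VTA, and of them Nr1d1 alone passed the test of a difference between tissues. Dbp reached 0.65 ± 0.04 with a peak at ZT12.8 (2.48-fold, limma adjusted p = 2.8e-05, 12 of 12 arrays). Ciart reached 0.66 ± 0.06 at ZT11.0 (adjusted p = 9.6e-04 in limma; 12 of 12) and Nr1d1 0.65 ± 0.05 at ZT10.0 (5.3e-05; 11 of 12). Arntl, the activator of the clock loop, peaked in antiphase at ZT24.0 (0.42 ± 0.05; limma adjusted p = 0.00667; 12 of 12 arrays). Fabp7 peaked at ZT3.2 (0.43 ± 0.04; limma adjusted p = 4.4e-04; 12 of 12 arrays). Immediate early genes and a heat shock gene peaked in the dark: Egr1 at ZT16.3 (0.50 ± 0.07; limma adjusted p = 0.0278; 10 of 12 arrays), Egr3 at ZT19.2 (0.34 ± 0.05) and Hspa1b at ZT18.2 (0.36 ± 0.05; limma adjusted p = 0.0177; 12 of 12 arrays).

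In PFC 31 genes passed, 10 with a peak in the light and 21 in the dark, with 2001 at an unadjusted p under 0.05. Of the 31, 13 peaked between ZT11 and ZT15. Core clock genes made up 7, of 21 measured, and 14 passed adjusted over the list alone (Fisher's exact test, adjusted p = 1.57e-13). Nr1d2 peaked at ZT12.4, Per3 at ZT13.9 and Usp2 at ZT10.0. Of 14 immediate early genes 2 passed, and 7 adjusted over the list alone (Fisher's exact test, adjusted p = 0.00295, and 0.127 with replicate number as a block). Of 10 heat shock genes 1 passed, and 1 adjusted over the list alone (0.154). The largest amplitudes among the genes named by rule were those of Astx5 (1.02 ± 0.15, ZT15.7, 4.12-fold; limma adjusted p = 0.0281; 12 of 12 arrays) and of Srsy (0.69 ± 0.10, ZT15.9; adjusted p = 0.0281 in limma; 12 of 12). Both belong to multi-copy families whose near-identical copies share probes, so these values are uncertain. These 2 genes stepped between the arrays of ZT11 to ZT19 and those of ZT23 to ZT07, which in both cycles were the first 3 and the last 3 times sampled; that step was called for 21 PFC genes. With replicate number as a block 20 genes passed, and Srsy (adjusted p = 0.0561) and Egr1 (0.0508) were lost in limma. A rank test and each cycle alone called 0 in PFC, with the same limits as in SN/VTA. The count was 15, 18 and 13 without ZT15, ZT19 and ZT07 of replicate 1, and 14, 14, 17, 18, 17 and 17 without ZT11, ZT15, ZT19, ZT23, ZT03 and ZT07 of replicate 2.

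In STR and HAB the same 3 clock genes passed in limma, Ciart, Dbp and Nr1d1. The number hung on the method, with 33 and 9 genes in the robust fit, 140 and 49 in 1 model of 48 arrays, 5 and 5 with a filter at the median, 2 and 2 with no filter or with the choroid plexus mean as covariate (chosen after the data were seen), and 0 and 3 in the F test over 6 times. In STR Ciart had an amplitude of 0.75 ± 0.07 with a peak at ZT10.5 (2.84-fold, limma adjusted p = 0.00335). Nr1d1 had 0.41 ± 0.04 at ZT8.2 (adjusted p = 0.0060 in limma) and Dbp 0.40 ± 0.05 at ZT11.0 (0.0219), each in 12 of 12 arrays. In HAB Ciart had 0.64 ± 0.08 at ZT11.5 (limma adjusted p = 0.0324, and 0.0682 with replicate number as a block). Dbp had 0.54 ± 0.06 at ZT11.0 (2.13-fold, adjusted p = 0.0139 in limma) and Nr1d1 0.46 ± 0.05 at ZT7.5 (0.0139), again in 12 of 12 arrays each. Arntl did not pass in STR (0.45 ± 0.06, ZT22.8; limma adjusted p = 0.058, and 0.0352 with the block) or in HAB (0.33, ZT23.8; 0.106). Core clock genes passed adjusted over the list alone for 12 of 21 in STR and 9 in HAB (Fisher's exact test on the 3 passing over all genes, adjusted p = 2.45e-08 in each). Other lists had none passing over all genes. Adjusted over the list alone, ER chaperones gave 5 of 13 in STR and 9 in HAB, heat shock genes 6 of 10 and 1, and glucocorticoid-responsive genes 7 of 12 and 0. At an unadjusted p under 0.05 there were 1467 genes in STR and 1089 in HAB. Leaving out the STR array of ZT07 replicate 2 left 1 gene in STR. In HAB 0 were left without the array of ZT11, ZT19 or ZT07 of replicate 1 or of ZT11 or ZT23 of replicate 2, 1 without ZT07 and 5 without ZT19 of replicate 2. A rank test and each cycle alone called 0 in both tissues. For so few genes the rank test could not have passed any on 12 arrays, and 1 cycle holds 1 array per time. All 8 choroid plexus genes differed between the replicate numbers of HAB at an unadjusted p under 0.05 in limma, with a median first minus second cycle of 1.64, against 0 of 13 habenula genes (0.0058), and 0 of the 8 had a rhythm there at an unadjusted p under 0.05 with or without replicate number as a block, at wide errors (Ttr 0.45 ± 0.27 with the block and ± 0.51 without).

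The overlap of SN/VTA and PFC held 8 genes, Ciart, Dbp, Fabp7, Hrh3, Nr1d1, Nr1d2, Per3 and Usp2, where independent lists would share 0.050. Ciart, Dbp and Nr1d1 passed in all 4 tissues.

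**Figure D2:**
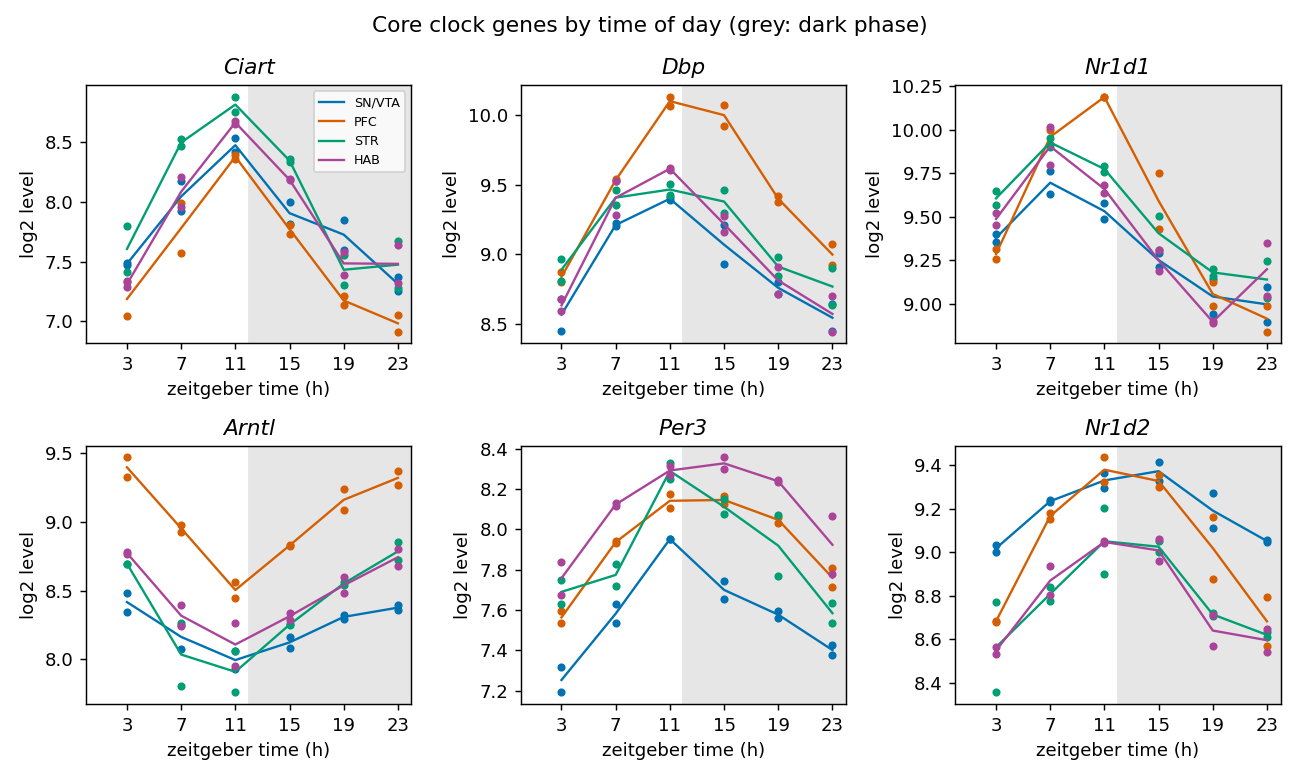
Log2 levels (vertical axis) of core clock genes against Zeitgeber time in hours (horizontal axis) in the 4 tissues; points are arrays, lines join the means of 2 arrays and grey marks the dark. Ciart has its highest mean at ZT11 in every tissue, where Arntl has its lowest.

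The third comparison took the 4 tissues together and asked which rhythms they shared. With tissue as a term over 48 arrays, 958 genes passed in limma, 486 with a peak in the light and 472 in the dark; 3305 had an unadjusted p under 0.05. The most frequent peak windows were ZT7 to ZT11 with 257 genes and ZT15 to ZT19 with 200. Ciart (0.64 ± 0.04, ZT11.0; limma adjusted p = 1.4e-16; 46 of 48 arrays), Dbp (0.50 ± 0.03, ZT11.6; 48 of 48) and Nr1d1 (0.45 ± 0.03, ZT8.7; 45 of 48) had the largest clock amplitudes, and Arntl peaked at ZT23.5 (0.35 ± 0.03). Fabp7 peaked early in the light, at ZT3.2 (0.36 ± 0.02; limma adjusted p = 3.5e-16; 46 of 48), and Cirbp late in the light, at ZT8.3 (0.30 ± 0.02; limma adjusted p = 2.3e-12; 43 of 48).

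Core clock genes passed for 15 of 21, and 17 adjusted over the list alone, 6 with a peak in the light and 9 in the dark (Fisher's exact test, adjusted p = 1.63e-13). They ran in order through the day, from Nr1d1 over Usp2 (ZT10.9), Bhlhe41 (ZT11.3), Per1 and Nr1d2 (ZT12.4), Per3 (ZT13.4) and Cry1 (ZT16.6) to Clock (ZT21.8; adjusted p = 0.0566 in limma with a random replicate block of sampling hour), Arntl and Nfil3 (ZT24.0). Csnk1e, Fbxl21, Hlf, Npas2, Rora and Rorb did not pass.

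Protein-folding genes peaked in the dark in 2 groups. Chaperones of the endoplasmic reticulum passed for 11 of 13, and 11 adjusted over the list alone, all peaking in the dark (Fisher's exact test, adjusted p = 2.42e-11). Fisher's test makes no allowance for list members that move together, so its p-values for the shared rhythm can be too small. Sdf2l1 peaked at ZT18.6 (0.33 ± 0.04; limma adjusted p = 7.7e-07; 41 of 48 arrays) and Hspa5, the main chaperone of this compartment, at ZT18.8 (0.25 ± 0.03; limma adjusted p = 1.9e-07; 41 of 48). Pdia6 peaked at ZT19.2 and Creld2 at ZT18.5. Heat shock genes passed for 6 of 10, and 9 adjusted over the list alone, all 6 in the dark (adjusted p = 5.89e-05). The inducible Hspa1b peaked at ZT16.9 (0.49 ± 0.08; limma adjusted p = 1.5e-04; 37 of 48), Dnajb1 at ZT17.3, Hspb1 at ZT19.5 and Hsph1 at ZT20.6.

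Glucocorticoid-responsive genes passed for 8 of 12, and 10 adjusted over the list alone, 4 in the light and 4 in the dark (Fisher's exact test, adjusted p = 4.79e-07), several of them close to lights off. Sgk1 peaked at ZT11.9 (0.33 ± 0.05; limma adjusted p = 1.7e-04; 35 of 48 arrays), Zbtb16 at ZT12.1 (0.30), Tsc22d3 at ZT13.5 (0.23) and Sult1a1 at ZT13.6 (0.19). Endothelial genes passed for 4 of 8, and 5 adjusted over the list alone, all 4 in the dark (adjusted p = 0.00522). The tight junction gene Cldn5 peaked at ZT22.8, the growth factor receptors Kdr at ZT23.4 and Flt1 at ZT21.1, and the transporter Slco1a4 at ZT12.5. Fmo2, a monooxygenase (0.41 ± 0.05, ZT14.0; limma adjusted p = 5.4e-06; 42 of 48 arrays), and Hif3a (0.34, ZT12.9) were also among the largest amplitudes.

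Immediate early genes passed for 3 of 14, and 6 adjusted over the list alone (Fisher's exact test, adjusted p = 0.31), all in the dark: Egr1 at ZT16.0 (0.21), Egr3 at ZT20.0 (0.18) and Homer1 at ZT19.7 (0.15). The cholesterol synthesis genes Insig1 (ZT6.8) and Lss (ZT8.5), the oligodendrocyte genes Mag (ZT7.8) and Mog (ZT8.8) and the astrocyte gene Gjb6 (ZT16.2) passed, the only members of their lists to do so, where 3 cholesterol, 2 oligodendrocyte and 2 astrocyte genes passed adjusted over the list alone. Cirbp was the 1 measured gene of the cold-inducible list. No gene of the remaining lists passed, which include dopamine synthesis and midbrain dopamine neurons (0 of 19, and 0 adjusted over the list alone), dopamine receptors and striatal signalling (0 of 15) and dopamine breakdown (0 of 4). The shared test fits 1 rhythm to all 4 tissues. For genes far higher in 1 tissue, such as Slc6a3 or Drd1, it therefore says little about a rhythm there. Of 51 genes called in at least 1 tissue alone, 39 were among the 958. A random block of sampling hour left 858 genes. Averaging the 4 tissues at each hour, tested over 12 values, left 133, the conservative count if the tissues came from the same mice, since the 48 arrays would then not be independent; the first cycle alone gave 199 and the second 70.

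**Figure D3:**
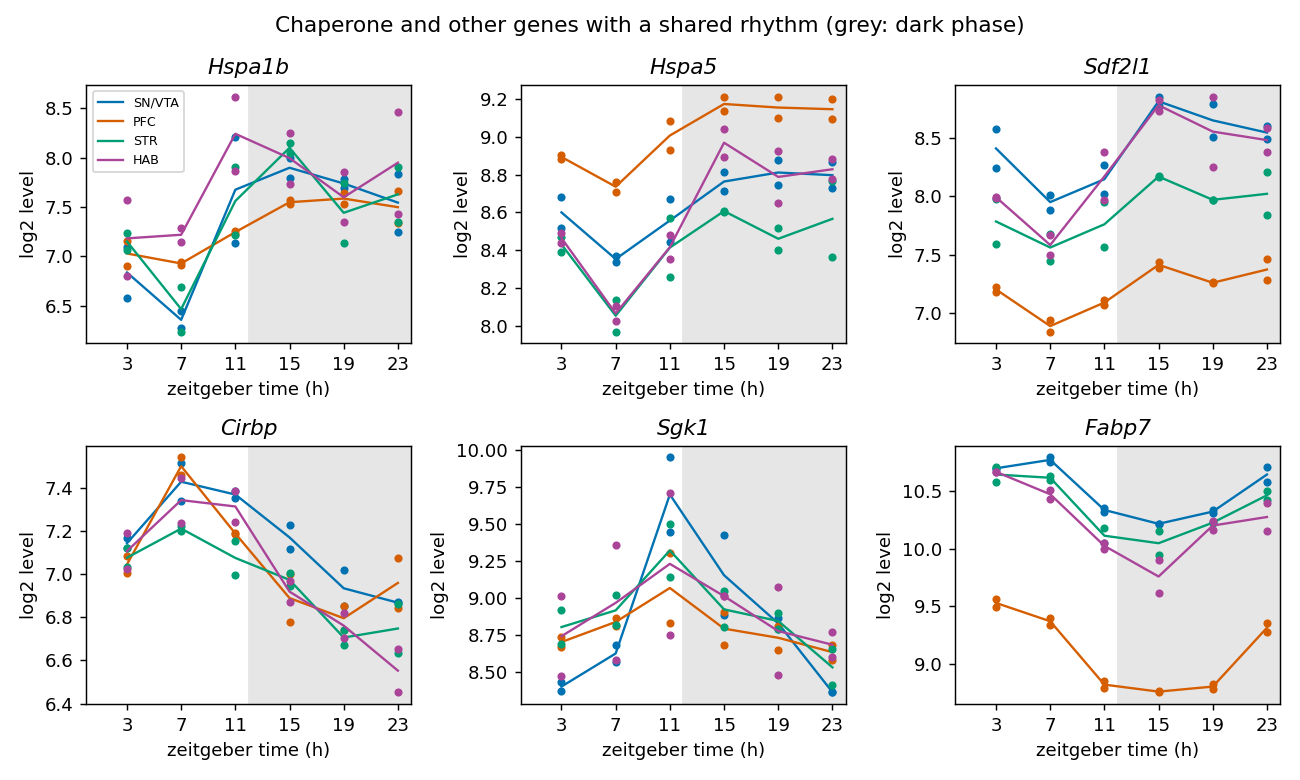
Log2 levels (vertical axis) of Hspa1b, Hspa5, Sdf2l1, Cirbp, Sgk1 and Fabp7 against Zeitgeber time in hours (horizontal axis) in the 4 tissues; points are arrays, lines join their means and grey marks the dark. Hspa5 and Sdf2l1 are high in the dark, with shared peaks at ZT18.8 and ZT18.6, and Fabp7 in the early light, with a shared peak at ZT3.2.

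The fourth comparison asked where a rhythm differed between tissues, and 5 genes passed in limma, Sf3a2, Syvn1, Nr1d1, Bmyc and Fam189b; 1147 had an unadjusted p under 0.05. The clock repressor Nr1d1 had its largest fitted amplitude and latest peak in PFC (limma adjusted p = 0.0061 for the difference), 0.65 at ZT10.0 against 0.35 at ZT8.3 in SN/VTA, 0.41 at ZT8.2 in STR and 0.46 at ZT7.5 in HAB. The other 4 had fitted amplitudes of 0.28 to 0.29 in PFC and smaller ones elsewhere. Sf3a2, a splicing factor (limma adjusted p = 0.0020), had 0.29 ± 0.04 with a peak at ZT13.9 in PFC and at most 0.10 in the other tissues, and Syvn1, a ubiquitin ligase of the endoplasmic reticulum (adjusted p = 0.0059 in limma), 0.29 ± 0.04 at ZT15.1 and at most 0.11. Bmyc (0.0119) had 0.29 ± 0.05 at ZT12.6 in PFC, and Fam189b (0.0404, and 0.120 with a replicate block of sampling hour) 0.28 ± 0.04 at ZT14.9. Sf3a2 and Fam189b were among the 21 PFC genes with the step between ZT11 to ZT19 and ZT23 to ZT07, as a measured fact beside their rhythm. Of 21 core clock genes, 1 passed, and 3 adjusted over the list alone (Fisher's exact test, adjusted p = 0.115). The simulated data gave more false calls for this test than its 5% target, 22 of 94. An interaction with no assumed shape called 2 genes, none of them among the 5, and without the PFC array of ZT23 of either replicate 3 genes passed.

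The fifth comparison set the dark against the light in each tissue. Chaperones of the endoplasmic reticulum were higher in the dark in all 4 tissues. Their median change was 0.20 in SN/VTA (camera in limma adjusted p = 1.22e-13, and adjusted p = 0.0749 with an estimated correlation), 0.17 in PFC (7.40e-12, and adjusted p = 0.00614 with an estimated correlation). It was 0.17 in STR (1.86e-07, and adjusted p = 0.248 with an estimated correlation) and 0.29 in HAB (4.63e-21, and adjusted p = 0.0749 with an estimated correlation). Of the 13, 12, 13, 11 and 13 changes lay above 0, and 10, 7, 8 and 10 genes passed adjusted over the list alone, none over all genes. Heat shock genes were higher in the dark too, with all 10 changes above 0 in each tissue. Their medians were 0.14 in SN/VTA (camera in limma adjusted p = 3.28e-05, and adjusted p = 0.104 with an estimated correlation), 0.08 in PFC (2.17e-04, and adjusted p = 0.0749 with an estimated correlation). They were 0.22 in STR (9.10e-08, and adjusted p = 0.0749 with an estimated correlation) and 0.18 in HAB (9.46e-08, and adjusted p = 0.0749 with an estimated correlation). In that order of tissues 3, 1, 5 and 6 passed adjusted over the list alone.

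Immediate early genes were higher in the dark in PFC, by a median of 0.34 (13 of 14 above 0, 10 adjusted over the list alone; camera in limma adjusted p = 1.49e-12, and adjusted p = 0.0749 with an estimated correlation). In STR they were higher by 0.25 (14 of 14, 6 adjusted over the list alone; 4.37e-10, and adjusted p = 0.0797 with an estimated correlation). Cholesterol synthesis genes were lower in the dark in 3 tissues, with medians of -0.05 in SN/VTA (8.94e-05, and adjusted p = 0.335 with an estimated correlation), -0.05 in PFC (0.0148, and adjusted p = 0.741 with an estimated correlation). In STR it was -0.12 (2.11e-04, and adjusted p = 0.126 with an estimated correlation). Of their 13 genes 4, 2 and 2 passed adjusted over the list alone. In HAB their median was 0.02, with no camera call (adjusted p = 0.335 in limma). In PFC dopamine receptor and striatal genes had a median of -0.12 (4.78e-04, and adjusted p = 0.248 with an estimated correlation) and oligodendrocyte genes of -0.13 (0.0175, and adjusted p = 0.757 with an estimated correlation), with 0 passing adjusted over the list alone in either. In HAB oligodendrocyte genes had a median of -0.14 (0.0329, and adjusted p = 0.906 with an estimated correlation) and habenula genes of 0.11 (0.0148, and adjusted p = 0.741 with an estimated correlation). In these HAB lists 0 genes passed adjusted over the list alone. Lists of neighbouring tissues had no camera call in HAB: choroid plexus genes had a median of 0.35 (adjusted p = 0.197, and 0.0129 with replicate number as a block), thalamus genes of 0.20 (0.154) and cortical neuron genes of -0.12 (0.109). The dark arrays of replicate 2 included ZT15, whose mean over the choroid plexus genes was 9.15, against 7.03 to 7.35 in the rest of that replicate. Cirbp, the 1 measured gene of its list, was lower in the dark by 0.32 in SN/VTA, 0.36 in PFC, 0.31 in STR and 0.51 in HAB, and did not pass over all genes in limma (adjusted p = 0.270, 0.271, 0.375 and 0.166).

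Few single genes passed over all genes. In SN/VTA the splicing regulator Tra2a was higher in the dark (0.38 ± 0.05), and the myelin gene Pllp (-0.40 ± 0.05) and Tnni1, a troponin (-0.33 ± 0.05), were lower, each with a limma adjusted p of 0.0276 and with all 6 dark arrays on that side of the light mean. In SN/VTA 0 genes passed with no filter, 0 without ZT11 and ZT23 and 0 with the choroid plexus mean as covariate (chosen after the data were seen). In PFC the lipase Lipg (0.42 ± 0.06) and P4ha1, a collagen prolyl hydroxylase (0.41 ± 0.06), were higher in the dark (adjusted p = 0.0321 in limma; 6 of 6 arrays). Neither passed with no filter (0 genes) or without ZT11 and ZT23, where 6 other genes did. At an unadjusted p under 0.05 there were 1244 genes in SN/VTA and 1390 in PFC. No gene passed in STR or HAB in limma, where 1445 and 974 had an unadjusted p under 0.05; the robust fit called 8 and 4, and 1 model of 48 arrays 44 and 12. In SN/VTA 0 were left without ZT11, ZT15, ZT19 or ZT23 of replicate 1 or ZT15, ZT19, ZT23 or ZT07 of replicate 2, 1 without ZT03 or ZT07 of replicate 1 or ZT11 of replicate 2, and 5 passed without ZT03 of replicate 2. In PFC 0 were left without any 1 array except ZT19 of replicate 1 (1 gene) and ZT11 of replicate 2 (2 genes).

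**Figure D4:**
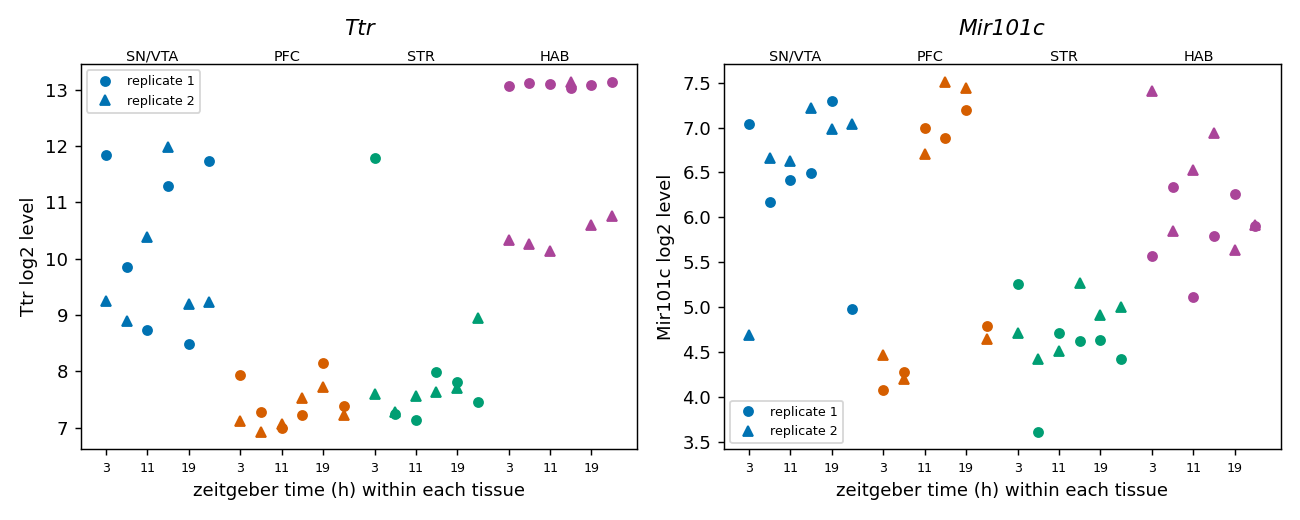
Log2 levels (vertical axis) of Ttr and of Mir101c, the gene with the largest PFC step (2.71 ± 0.15), in single arrays against Zeitgeber time in hours within each tissue (horizontal axis); circles are replicate 1 and triangles replicate 2. Ttr in HAB lies at 13.0 to 13.1 in the 6 arrays of replicate 1 and in ZT15 of replicate 2, and at 10.1 to 10.8 in the other 5.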

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

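Chosen only after the result was seen were the tests of the choroid plexus genes by replicate number and by time of day, and of the size of the PFC step in the other tissues, and the step in PFC was itself looked for after the values were seen; the other tests here were chosen before.

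The rhythm of 5 genes differed between tissues in limma: Sf3a2 (adjusted p = 0.00204), Syvn1 (0.00593), Nr1d1 (0.00606), Bmyc (0.0119) and Fam189b (0.0404). For P4ha1, 1 PFC array in the light stood apart from the other 5, with a gap of 0.838 of the range. The rule flags gaps that arise by chance in about 1 of 20 groups, and 10 groups were tested. How rare a gap of 0.838 is was not worked out.

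Some PFC genes separated the arrays of ZT11 to ZT19 from those of ZT23 to ZT07: 21 passed that step in limma, against 0 or 1 in each other tissue. At an unadjusted p under 0.05 the same step had 9.25% of all genes in PFC and 9.44% in SN/VTA, so the share over all genes does not set PFC apart. The 21 include Mir101c (2.71 ± 0.15), Astx5 (1.53), Srsy (1.06), the vomeronasal receptor gene Vmn1r94 (0.77), Jun (0.50), Sf3a2 (0.39) and Fam189b (0.38). In HAB the first 3 of these differed together between arrays of the same time. Mir101c, Astx5 and Srsy were at 5.56, 5.60 and 5.43 in ZT03 of replicate 1 and at 7.40, 7.13 and 7.11 in ZT03 of replicate 2. A batch of PFC arrays that ran with the times would move genes not used by the brain as well, and 9.95% of 191 olfactory and vomeronasal receptor genes had a step at p under 0.05 (95% exact interval 6.10 to 15.1), against 9.25% of all genes. The share does not mark the PFC step, as it was 12.0% for the same times in STR (6.45% of all genes) and 11.0% for ZT19 to ZT03 in PFC, with 0 genes called in each. A 24-h rhythm that the other tissues share would move the same genes there, and 71.4% (15 of 21) went the same way in their mean. Their step was 0.28 for Mir101c, -0.01 for Astx5 and 0.01 for Jun and Sf3a2, but -0.44 for Fabp7 against -0.61 in PFC. For 95.2% (20 of 21) its upper 95% limit lay under 0.5 times the PFC step, which argues against a rhythm of like size in the other tissues except for Fabp7, and leaves a smaller one open. The 21 genes were picked by their PFC step, which can overstate its size. Batch and time cannot be told apart, because in both cycles the high arrays were the first 3 sampled, and a rhythm of PFC alone stays open as well.

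Choroid plexus genes were higher and more spread in HAB. A 24-h rhythm as the source of the whole spread is argued against, since over the same 6 times 8 of 8 genes differed between the cycles by more than 2 SE. A rhythm beside that difference stays open. With replicate number as a block 0 of 8 had p under 0.05 in limma, but the errors were wide (Ttr 0.45 ± 0.27). In dark against light camera passed with the block (adjusted p = 0.0129), not without (0.197). That call does not tell a rhythm from 1 dark array, ZT15 of replicate 2. Its mean over the choroid plexus genes was 9.15, against 7.03 to 7.35 in the rest of replicate 2. In replicate 1 that mean was 8.82, 9.06 and 9.21 in the dark and 9.10, 8.98 and 9.26 in the light. A varying amount of choroid plexus in the HAB dissections is a candidate explanation: 8 of 8 genes differed between the replicate numbers in 1 direction, where 0 of 13 habenula genes did. Ttr, with the highest array level of them, was at 13.0 to 13.1 in the 6 arrays of replicate 1 and in ZT15 of replicate 2. It was at 10.1 to 10.8 in the rest, and a change between the study's days, or ZT15 of replicate 2 standing with the other cycle, stays open. No biological explanation was tested beyond the rhythm.

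Far more genes passed over the 4 tissues together (958) than in any tissue alone (31 at most). Noise shared by the tissues of the same animals is argued against for most of the 199 genes called in the first cycle, since 92.0% of them peaked within 6 h of the same time in the second, whose animals differed, against 56.2% of all genes; for the rest of the 958 it stays open. More arrays in the joint test stay a possible reason. In data simulated with the shared amplitudes, the single tissue with the most calls, SN/VTA, had 11.1% of those of the joint test (84 of 758). The simulation cannot decide this, since it took amplitudes fitted to these same genes (median 0.11), alike in all tissues, with noise independent between tissues. It also called 84 genes in SN/VTA where the data gave 28. Rhythms of single genes that differ in size between tissues stay open.

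Counts were set against other splits of the samples, 100 for each result with the real one included, so 1 of 100 is the lowest share possible. The tissue contrasts could hardly come out otherwise, since all 12 arrays of each tissue correlated best with that tissue. A count also does not clear its single genes of chance: the test of a difference had 22 false of 94 simulated calls. The real split alone gave as many rhythmic genes in SN/VTA (28, highest other 1), PFC (31 and 1), STR (3 and 1) and HAB (3 and 1), in the shared rhythm (958 and 143), in the difference between tissues (5 and 2) and in the tissue contrasts of SN/VTA (613 and 66), PFC (911 and 136), STR (377 and 69) and HAB (359 and 0), so 1 of 100 in each. For dark against light 1 split of 100 was as large in SN/VTA (3 genes, highest other 2) and 3 in PFC (2 and 2). In STR and HAB the real count was 0, so all 100 splits were as large; the highest other was 0 in STR and 100 genes in HAB. That HAB split had 6 of the 7 arrays with high Ttr on 1 side and called 7 choroid plexus genes, which points to a structure of the samples.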

How the results depend on the processing

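Chosen only after the data were seen were the tissue mean per hour, the choroid plexus covariate, and the tissue contrasts without short RNA genes or within 1 cycle with additive times.

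The total counts of the tissue contrasts stayed within 1.5 times under each alternative run. Without single arrays or 1 cycle they ranged from 597 to 623 in SN/VTA, 874 to 958 in PFC, 370 to 397 in STR and 343 to 387 in HAB. Their split by direction moved more in SN/VTA, where centring took 389 higher and 224 lower to 639 and 143. The counts of rhythmic genes in 1 tissue did not stay within 1.5 times. In the order SN/VTA, PFC, STR and HAB, against 28, 31, 3 and 3, the robust fit gave 167, 231, 33 and 9 genes, 1 model of 48 arrays 17, 239, 140 and 49, and a filter at the median 50, 77, 5 and 5. The rank test gave 0 in all 4 tissues, with 1460, 1721, 1172 and 1064 genes at its own unadjusted p under 0.05. On 12 arrays its lowest possible p, adjusted over 6 phases and 17274 genes, falls under 0.05 only if several genes reach it. A 0 could therefore hardly be avoided in STR and HAB, and says little in any tissue. With no filter there were 12 in SN/VTA and 20 in PFC, with centred arrays 13 in SN/VTA, and with the F test over 6 times 3 in SN/VTA, 9 in PFC and 0 in STR. Without single arrays or 1 cycle counts ranged from 0 to 21, 0 to 26, 0 to 3 and 0 to 5, each 0 coming from 1 cycle alone and in HAB also from single arrays. Replicate number as a block gave 18 in SN/VTA and 20 in PFC, and moved the camera calls from 51 to 52. The shared rhythm had 971 genes with it, 942 of them among the 958. Blocks also moved named genes and lists, as given beside their results.

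For dark against light in SN/VTA (3 genes) no filter, leaving out ZT11 and ZT23 and the choroid plexus covariate each gave 0, the robust fit 34 and 8 groups of 48 arrays 5; without arrays or 1 cycle the range was 0 to 5. In PFC (2 genes) no filter gave 0, the median filter 1, the robust fit 15, the 8 groups 41 and leaving out ZT11 and ZT23 6 (0 of the 2 kept), with a range of 0 to 2. In STR (0 genes) the robust fit gave 8 and the 8 groups 44, and in HAB (0 genes) 4 and 12, and the covariate 1.

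The shared rhythm (958) fell to 133 on tissue means, 407 without SN/VTA, 440 without PFC and 510 without STR, all with fewer values in the test, and to 70 and 199 in 1 cycle. The difference between tissues (5) gave 8 in the robust fit, 2 with no assumed shape and 0 to 7 without arrays or 1 cycle. Of the 51 camera calls 10 held with an estimated correlation. Named genes kept their side of the threshold in 8486 cases, gained it in 62, lost it in 543 and reversed in 0. Except where fewer genes or samples entered a test, the cause was not tested. No measure of signal over background was used, so the limit it sets is unknown.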

Other observations

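Chosen only after the result was seen were the tests of a later core clock in PFC, of gene families and of unnamed rows, and the look at small nucleolar RNAs.

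Small nucleolar RNAs, which guide the modification of ribosomal RNA, were higher in PFC than in the other tissues for 21 of 65 genes and lower for 5 in limma, with a median difference of 0.63 (0.61 after quantile normalization and 0.63 after centring). Snord61 was higher by 5.22, Snord110 by 5.17, Snord58b by 5.06 and Snord22 by 4.88. The median PFC difference was 0.03 over 260 other short RNAs, -0.18 over 15 host genes taken by Snhg or Gas5 symbols and -0.05 over 1284 genes of matched level. Of the 260, 251 were Mir genes, so they say little about how small nucleolar RNAs were recovered from each tissue. Tissue and its RNA preparation cannot be told apart here. Hosts of the single small nucleolar RNAs named here were not looked up, so their levels are left open. In HAB 0 were higher and 13 lower, in SN/VTA 2 and 9, and in STR 1 and 10.

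Among 195 gene families grouped by the letters of their symbols, 1 held more genes of the shared rhythm than the rest in Fisher's exact test: 6 of 13 Hspa genes passed, all with a peak in the dark, where 0.721 were expected (adjusted p = 0.00684). This family holds chaperones of several compartments and overlaps the heat shock and ER chaperone lists. In a shared rhythm test over all rows, 582 of 23521 rows with 1 symbol passed (2.47%), 35 of 1814 with several (1.93%) and 56 of 16010 unnamed here (0.350%).

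A later phase of the core clock genes in PFC is a hypothesis raised by the peaks of Nr1d1 and Dbp. Over 15 core clock genes of the shared rhythm, PFC peaked a mean of 0.589 h later than the other tissues (0.388 h in the first cycle, 0.533 h in the second and 0.492 h without Nr1d1). A permutation test, with tissue names permuted within sampling hours 10000 times, gave p = 0.110, and 0.439 adjusted over the 4 tissues, so the data do not settle it.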
